A study of Mus musculus with 8 samples.

How the data were processed

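The series holds 7 bulk mRNA-seq libraries of mouse mPFC and 1 single-nucleus sample of prefrontal cortex. Per the labels' protocols, GFP-positive mPFC tissue expressing an AAV-delivered hairpin was taken from brain slices, RNA was purified, and a sequencing service made the libraries. The deposited table gives whole-number read counts per gene for the 7 bulk libraries. Per the submitters' processing notes, STAR 2.7.1a, Picard and HTSeq 0.9.1 were used with the mm10 genome. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and members of near-identical families such as ribosomal proteins are uncertain where reads could be shared with pseudogenes. For the single-nucleus sample the processing notes name Cell Ranger 6.1.2 and Seurat 4.1.0, and its expression is not analysed here.

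The table has 22000 rows named by gene symbol, of which 4507 had no count in any library. In 27 rows the gene symbol had been turned into a calendar date, as spreadsheet programs do, and 2 of these names stood on more than 1 row. They held 0.295% to 0.347% of the counts. They stayed in the library totals and in the tests and are not named. The 13 mitochondrially encoded mRNAs were listed at 0 in every library, so that list could not be tested. Symbols were matched to GENCODE M21 (GRCm38) for gene positions, transcript length and GC content, using the longest coding transcript. That matched 19588 symbols (89.0%), and 13532 tested genes (94.7%) had a length. It may not be the annotation the authors used.

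Groups came from the library titles. The titles do not say that libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per gene between 14.4 and 240, and none were duplicates of each other. Total counts were 15947437, 17145606, 18548359 and 17798527 for Scramble shRNA 1 to 4 and 16730484, 15891766 and 19139807 for Npas4 shRNA 1 to 3. Intervals made from counts cover counting error only.

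The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest in R 4.3.3) on the deposited counts, with TMM normalization, genes kept by filterByExpr, no covariate and Benjamini-Hochberg adjusted p below 0.05 over 14292 genes. Log2 fold changes are Npas4 shRNA minus Scramble shRNA. Npas4 was also tested by an exact two-sided permutation test of log2(CPM + 1). Gene lists, 24 of pathways and complexes and 18 of cell types, were tested with limma 3.58.1 camera at its preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 5 tested genes. Of 42 lists 41 could be tested. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, were run beside it. They were run with all 7 libraries only, with no covariate, with the library set described below as a term or with the replicate block. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined, and the comparisons that use the library sets were added afterwards. By that rule the text may name Npas4, up to 12 genes in each direction past the threshold, the 10 smallest p where fewer than 10 pass, and up to 4 members of each list with the smallest p, which gave 161 genes. The text names a part of these. Mbp, Ifit1 and Gabrb2 fall outside it and were chosen after their values were seen.

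Library sets were read from the sign of the first principal component of log2 CPM, which took 72.9% of the variance, the next component taking 8.28%. They coincide with the replicate numbers, 1 and 2 against 3 and 4, and each holds libraries of both groups. The replicate numbers were checked as pairs. Deviations from the group means of same-numbered libraries correlated at 0.472, 0.708 and 0.700 for numbers 1, 2 and 3 across genes, so the numbers were taken to pair the libraries by the rule set in advance. The library sets alone can give this pairing. Once the mean of each group within each set was removed, numbers 1 and 2 each correlated at -0.18. With 2 libraries of each label in set A these are a single value by construction, and number 3 gave none. That value shows no pairing beyond the set but is too little to exclude it. In the block fit Scramble shRNA 4 has no partner and adds nothing to the difference.

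Alternatives were DESeq2 1.42.0 size factors, library totals or upper quartile in place of TMM, the DESeq2 Wald test, limma-voom, no filter on low counts, CPM above 1 in at least 3 libraries, the replicate number as a block, 1 surrogate variable from sva 3.50.0, adjusted p thresholds of 0.1 and 0.01, a glmTreat fold of 1.2, and leaving out each library in turn. Alternatives for normalized values were not run, since the table holds counts. Chosen after seeing the data were the library set as a term, each set alone, a correction of each library for transcript length and GC content (lowess, span 0.3) with the set term or the block, and the set term without Scramble shRNA 3 or 4. Figures were drawn with matplotlib 3.10.9.

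The tests were tried on simulated counts drawn from the libraries' own means and spread over 14165 genes, 100 changed 2-fold and 100 changed 4-fold. For this comparison the test with no covariate recovered 1 of the 2-fold and 33 of the 4-fold changes, with 0 unchanged genes called. With the library set as a term it recovered 76 and 93, with 10 unchanged genes called, and with the replicate block 74 and 91, with 16 unchanged genes called. On simulated lists limma camera gave 4.35e-20 for a changed list and 0.463 for an unchanged list. Each gene was drawn independently, so this cannot show how camera at its preset correlation behaves on genes that vary together.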

Results

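Messenger RNA was sequenced from the medial prefrontal cortex (mPFC) of C57BL/6J mice that had received an adeno-associated virus (AAV) carrying a short hairpin RNA (shRNA). The hairpin was directed against Npas4 or was a scrambled control. Npas4 encodes a bHLH-PAS transcription factor that neurons make in response to activity. The RNA came from GFP-positive pieces of mPFC cut from brain slices, so each library measured the mixture of cells in such a piece. There were 4 libraries labelled Scramble shRNA and 3 labelled Npas4 shRNA. The gene counts summed to between 15891766 and 19139807 per library, and between 15759 and 16267 genes had at least 1 count. The design text names 1 comparison, of mRNA levels between the hairpin against Npas4 and the scrambled hairpin, and 14292 genes had enough counts to be tested.

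The targeted gene was examined first. Npas4 lies on the minus strand of chromosome 19 from 4984355 to 4990316 in GRCm38, the assembly also called mm10. Its mRNA was not lower in the libraries labelled Npas4 shRNA. Its level, as CPM from the library totals, was 14.5 ± 5.19 (SD, n = 4) in the Scramble shRNA libraries and 15.8 ± 8.66 CPM (SD, n = 3) in the libraries labelled Npas4 shRNA. Scramble shRNA 1 to 4 held 13.8, 8.75, 14.1 and 21.4 CPM of Npas4, and the libraries labelled Npas4 shRNA 1 to 3 held 11.1, 10.5 and 25.8 CPM. These values rest on 150 to 494 counts per library. The fitted fold was 1.10, with a 95% interval from 0.591 to 2.05 (edgeR quasi-likelihood test, log2 fold change 0.14 ± 0.38 SE, adjusted p = 1). An exact two-sided permutation test of log2(CPM + 1) over the 35 splits of the libraries gave p = 0.943, where the smallest possible p was 0.0286. Neither test takes account of the library sets described below, between which Npas4 differed (set B minus set A, log2 fold change 0.73, edgeR adjusted p = 0.0243). The sets were read from the same data, so that p is descriptive. With the set as a term the fold was 1.14, with a 95% interval from 0.777 to 1.66 (edgeR adjusted p = 0.78). The log2 fold change was -0.13 within set A and 0.61 within set B, which holds a single library labelled Npas4 shRNA. The sign changed when single libraries were left out. The log2 fold change was -0.37 without Npas4 shRNA 3 and -0.02 without Scramble shRNA 2. Leaving out either spreads the labels less evenly, with a larger share of Scramble shRNA than of the other label in set B, where Npas4 was higher. These values therefore mix the label with the sets. Values given below without Npas4 shRNA 3 or Scramble shRNA 1 or 2 do so too, for genes and lists that differed between the sets. Because the target was not lower in these libraries, each direction given from here on follows the label alone, and the libraries are called "labelled Npas4 shRNA".

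**Figure D1:**
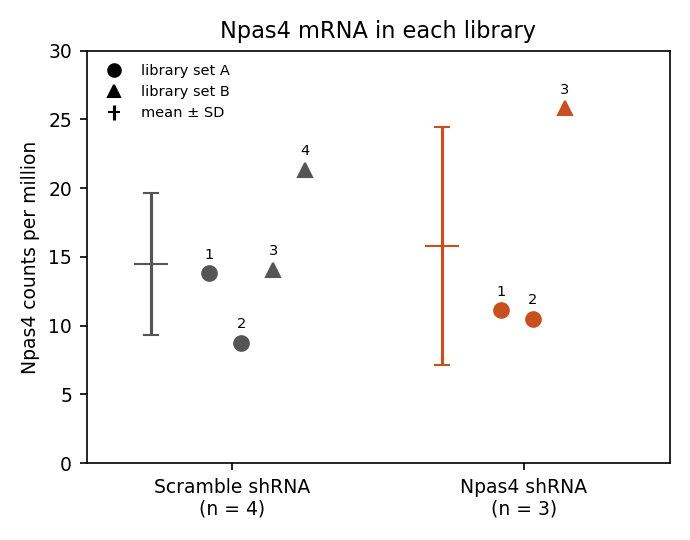
Npas4 mRNA in CPM in each of the 7 libraries, with the replicate number beside each point, the mean ± SD of each group at its left, and the marker shape giving the library set. The 3 libraries labelled Npas4 shRNA sit at 11.1, 10.5 and 25.8 CPM, within and above the range of 8.75 to 21.4 CPM of the 4 Scramble shRNA libraries.

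The largest difference among the libraries did not follow the hairpin. The first principal component of the log2 CPM values held 72.9% of their variance and separated replicates 1 and 2 of both groups from the other 3 libraries. The first 4 libraries are called library set A (Scramble shRNA 1 and 2, Npas4 shRNA 1 and 2) and the others library set B (Scramble shRNA 3 and 4, Npas4 shRNA 3). Between the sets 8988 genes differed past the threshold, of which 4597 were higher and 4391 lower in set B (edgeR quasi-likelihood test with the hairpin in the model). The sets were read from these same values, so the count describes the difference and is not an independent test of it. The GABA-A receptor subunit gene Gabrb2, chosen after its values were seen, averaged 2.22 CPM in set A and 82.8 CPM in set B. The difference followed transcript length, with a median log2 change from set A to set B of -1.52 over 602 genes with transcripts under 1000 nt and 0.75 over 3034 genes with transcripts over 5000 nt. Across 13532 genes, which are not independent replicates, Spearman's rho between length and this change was 0.653. Short transcripts under 1000 nt took 5.16% to 6.87% of the counts in set A and 1.92% to 2.47% in set B. Within each set the hairpin comparison followed length as well, less steeply, with a median of -0.38 in set A and -0.19 in set B for transcripts under 1000 nt.

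**Figure D2:**
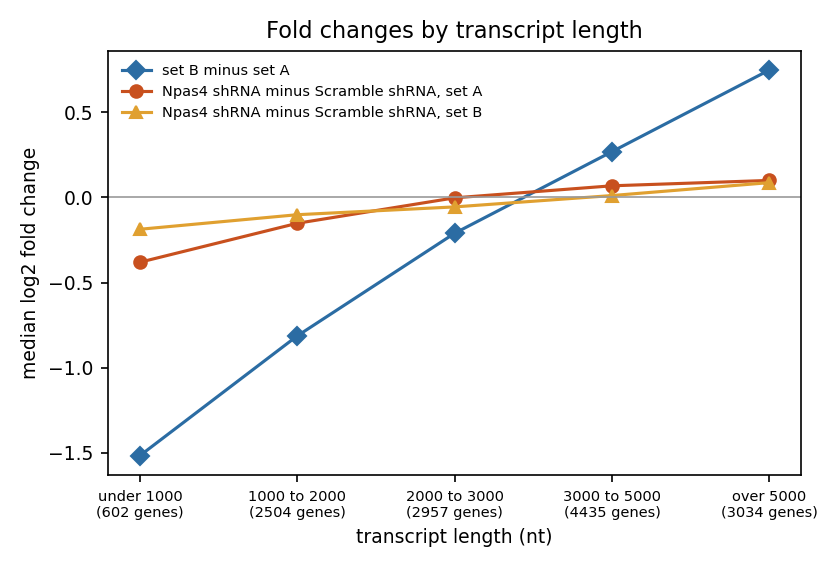
Median log2 fold change of genes grouped by transcript length in nucleotides, for library set B minus set A (diamonds) and for libraries labelled Npas4 shRNA minus Scramble shRNA within set A (circles) and within set B (triangles). The change between the sets runs from -1.52 under 1000 nt to 0.75 over 5000 nt, and the hairpin comparison runs from -0.38 to 0.10 in set A and from -0.19 to 0.09 in set B.

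No single gene passed the threshold between the 2 labels. Of the 14292 genes tested, 0 were higher and 0 lower in the libraries labelled Npas4 shRNA (edgeR quasi-likelihood test, adjusted p below 0.05). At an unadjusted p below 0.05 there were 61 genes, 19 higher and 42 lower, against 715 expected by chance. This test leaves the difference between the library sets in its spread, so the low count does not show that the labels differ less than chance. DESeq2 and limma-voom also called 0 genes, with 126 and 58 genes at an unadjusted p below 0.05. The fits that took the library set into account called 0 genes too. The set as a term gave 1741 genes at an unadjusted p below 0.05 and the replicate number as a block gave 1618, each against the same 715. Their smallest adjusted p values were 0.308 and 0.346. With a correction for transcript length and GC content the counts at an unadjusted p below 0.05 were 1169 and 1110. Genes are not independent of each other, so 715 is a rough guide. Within set A alone there were 1989 such genes and within set B alone 389, where a single library carried the Npas4 shRNA label.

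The 10 genes with the smallest p did not pass the threshold, and all had an adjusted p of 1. Among them, Arc, whose product acts at synapses and whose mRNA is induced by neuronal activity, averaged 46.8 ± 7.81 CPM in the Scramble shRNA libraries and 87.3 ± 21.1 CPM in the libraries labelled Npas4 shRNA. Its log2 fold change was 0.90 ± 0.25 SE, and it was higher in each of the 3 libraries labelled Npas4 shRNA than in any Scramble shRNA library. The copine gene Cpne4 averaged 53.02 ± 5.35 CPM against 76.0 ± 5.48 CPM, again without overlap. Fstl1, which encodes a secreted glycoprotein, averaged 37.4 ± 9.47 CPM in the Scramble shRNA libraries and 23.2 ± 0.855 CPM in those labelled Npas4 shRNA. Zfp618 averaged 5.26 ± 0.688 CPM against 2.68 ± 0.524 CPM. The other 6 were sparse, at 1.71 CPM or less in both groups. Their log2 fold changes were -2.99 for the zinc transporter gene Slc39a5, -2.04 for Nppa, which encodes atrial natriuretic peptide, -1.71 for Spata3, -1.52 for AC124992.1, -1.44 for Wnt5b and -1.52 for the cell-cycle gene Cdca3. Each of the 10 had the same sign in both library sets. They were ranked by p over these same libraries, which favours equal signs and a lack of overlap, so neither is separate support.

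Gene lists fixed in advance were then compared with all other genes by limma camera with its preset correlation of 0.01. Of 41 lists tested, 16 passed an adjusted p of 0.05, 5 of them higher and 11 lower in the libraries labelled Npas4 shRNA. With the correlation between genes estimated from the data, and by fry, 0 of the 41 lists passed. Without the library set in the model no member of any list passed the threshold, whether adjusted over all genes tested or adjusted over the list alone. With the set as a term none passed over all genes, and 12 lists had at least 1 member past the threshold adjusted over the list alone. A list score below is the mean log2 CPM of its tested genes relative to the mean of the 7 libraries. Members named by the rule had the smallest p in these libraries, so a lack of overlap among them is not separate support.

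Genes that neurons induce on activity scored higher in the libraries labelled Npas4 shRNA. The score of 24 activity-induced transcription factors was -0.109 ± 0.111 (SD, n = 4) in the Scramble shRNA libraries and 0.145 ± 0.031 (SD, n = 3) in the libraries labelled Npas4 shRNA, without overlap. Of the 24 genes, 18 had a log2 fold change above 0 and 15 were above 0 in both library sets. Bhlhe40, a transcriptional repressor, averaged 116 ± 11.7 CPM against 167 ± 14.2 CPM, and the immediate early genes Nr4a1 and Egr3 had log2 fold changes of 0.62 and 0.53. Maff went the other way, with a log2 fold change of -1.50 at about 1 CPM. The list's camera adjusted p was 9.63e-06 and its adjusted p = 0.155 with an estimated correlation. An exact two-sided permutation test of the score gave p = 0.0571, or 0.987 after Benjamini-Hochberg adjustment over the 41 lists. Camera gave an adjusted p of 0.00148 with the library set as a term (adjusted p = 0.72 with an estimated correlation) and 0.054 within set A, where it did not pass. The score difference was 0.253 with all libraries, 0.246 within set A and 0.265 within set B, which holds a single library labelled Npas4 shRNA. The markers of cortical excitatory neurons scored higher as well, by 0.229 against 0.253 for this list.

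The 34 activity-induced effector genes scored -0.080 ± 0.153 (SD, n = 4) and 0.107 ± 0.068 (SD, n = 3), with 27 members above 0. Besides Arc, the phosphatase gene Dusp1 had a log2 fold change of 0.51, and 0.30 without Npas4 shRNA 3. The camera adjusted p was 1.15e-04, and the adjusted p = 0.296 with an estimated correlation. It was 0.015 with the library set as a term (adjusted p = 0.72 with an estimated correlation) and 0.329 within set A, where it did not pass and the score difference was 0.114 against 0.187 with all libraries. The circadian clock list of 21 genes, which shares members with the first list, Bhlhe40 among them, also scored higher, from -0.048 ± 0.100 (SD, n = 4) to 0.064 ± 0.016 (SD, n = 3). Its camera adjusted p of 0.0236 became 0.0877 with the replicate block, 0.11 within set A and 0.156 with the set as a term and a correction for length and GC content, and it was an adjusted p = 0.433 with an estimated correlation. The clock score difference was 0.113 with all libraries, 0.118 with the block and 0.167 within set A. It ranged from 0.064 without Scramble shRNA 2 to 0.143 without Scramble shRNA 3. With the set as a term the median log2 fold change went from 0.0958 to 0.05 on correction for length and GC content. The clock call was also lost without Scramble shRNA 2, Scramble shRNA 4, Npas4 shRNA 2 or Npas4 shRNA 3, where the adjusted p was 0.37, 0.0598, 0.0972 and 0.258.

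Genes that other studies reported as NPAS4 targets did not differ as a list. Of 20 such genes, 11 had a log2 fold change above 0 and 9 below 0, with a median of 0.01 and a camera adjusted p of 0.535. Several of them, Plk2 and Pcsk1 included, are also in the list of activity-induced effector genes, so these lists are not separate groups of genes. Plk2 and Pcsk1 had log2 fold changes of 0.27 and 0.28, which ranged from 0.08 to 0.39 and from 0.15 to 0.49 over the left-out libraries, lowest without Npas4 shRNA 3. Nrp1, a receptor for semaphorins, had -0.53. The 17 genes of the bHLH-PAS family and its partners did not pass without the library set in the model (adjusted p = 0.586). They scored higher with the set as a term (adjusted p = 0.015) and with the replicate block (adjusted p = 0.00892), and by neither fit with an estimated correlation, where the smallest adjusted p of any list was 0.72 and 0.793. With a correction for transcript length and GC content the call with the set as a term was lost (adjusted p = 0.11) and the median went from 0.18 to 0.08, while the call with the replicate block was kept (adjusted p = 0.0473). Npas2 and Npas3, both members of this list, had log2 fold changes of 0.31 and -0.35, which were 0.01 without Npas4 shRNA 3 and -0.21 without Npas4 shRNA 1. The NuA4-TIP60 complex had an adjusted p of 0.24 over 18 genes.

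Markers of cortical excitatory neurons scored higher in the libraries labelled Npas4 shRNA, and markers of several other neuron classes scored lower. The 12 excitatory markers scored -0.098 ± 0.284 (SD, n = 4) and 0.131 ± 0.089 (SD, n = 3), and 11 of them were above 0. Arpp21 averaged 376 ± 63.3 CPM against 500 ± 52.0 CPM, and the transcription factor gene Neurod6 averaged 129 ± 14.7 CPM against 167 ± 12.4 CPM, both without overlap. The camera adjusted p was 2.26e-04, the adjusted p = 0.325 with an estimated correlation, and 0.0951 without Scramble shRNA 3. Leaving out that library took the score difference from 0.229 to 0.118. Within set A the score difference of the excitatory markers was 0.038 (adjusted p = 0.615), and in set B, with a single library labelled Npas4 shRNA, it was 0.396. Upper-layer markers had an adjusted p of 0.0478 with 11 of 14 genes above 0, and the adjusted p = 0.433 with an estimated correlation. The score difference of the upper-layer markers was 0.145 with all libraries, 0.137 with the library set as a term and 0.152 with the replicate block. The call was lost in both of these fits (0.186 and 0.22) and without any of Scramble shRNA 2, 3 or 4 and Npas4 shRNA 2 or 3 (0.0932 to 0.466). Over the left-out libraries the upper-layer score difference ranged from 0.068 without Npas4 shRNA 2 to 0.226 without Npas4 shRNA 1. With the set as a term the median log2 fold change went from 0.155 to 0.0442 on correction for length and GC content.

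Layer 6 markers scored lower, at 0.102 ± 0.428 (SD, n = 4) and -0.137 ± 0.345 (SD, n = 3). The layer 6 transcription factor gene Foxp2 had a log2 fold change of -0.63, and the matricellular gene Ctgf had -0.76. Foxp2 was -0.38 without Npas4 shRNA 1, and Ctgf was -0.21 without Scramble shRNA 3, which held 50.7 CPM of it against 18.5 CPM or less in the other 6 libraries. The camera adjusted p of 0.00361 became 0.0552 with the replicate block, 0.253 with the library set as a term and 0.25 without Scramble shRNA 3, and it was an adjusted p = 0.433 with an estimated correlation. The layer 6 score difference was -0.239 with all libraries, -0.22 with the block, -0.14 with the set as a term and -0.055 without Scramble shRNA 3. Layer 6 calls were also lost without Npas4 shRNA 1 or 2 (0.208 and 0.0518). Interneuron markers had an adjusted p of 0.0478, 0.0742 with the replicate block and an adjusted p = 0.433 with an estimated correlation. Their score difference was -0.136 with all libraries and -0.226 with the block, and ranged from -0.234 to -0.059 over the left-out libraries. The call was kept in 4 of 22 other settings. Among them the GABA synthesis gene Gad2 averaged 195 ± 109 CPM against 132 ± 34.2 CPM, the GABA transporter gene Slc32a1 had a log2 fold change of -0.41 and the neuropeptide gene Tac1 had -0.65. Without Scramble shRNA 3, which held 353 CPM of Gad2 and 174.0 CPM of Slc32a1, the log2 fold changes of these 2 genes were -0.13 and -0.22. Layer 5 markers did not pass (adjusted p = 0.787), although the layer 5 gene Tshz2 had a log2 fold change of -0.42 and was lower in each of the 3 libraries labelled Npas4 shRNA.

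Markers of oligodendrocytes and of tissue outside the cortex scored lower in the libraries labelled Npas4 shRNA, and Scramble shRNA 3 had the highest score for each list named here. Its scores were 0.964 for 24 oligodendrocyte markers, 0.854 for 16 striatal projection neuron markers and 0.992 for 14 markers of the olfactory bulb and subventricular zone. They were 0.779 for 14 thalamic and subcortical markers and 0.953 for 9 markers of choroid plexus and ependyma. The highest of these scores in any other library was 0.326. The myelin gene Mbp, chosen after its values were seen, stood at 2343 CPM in Scramble shRNA 3 and between 529 and 909 CPM in the other 6 libraries. Mag and Mog, also myelin genes, had log2 fold changes of -0.68 and -0.80. The dopamine receptor gene Drd2 had -0.97, the adenosine receptor gene Adora2a -1.24 and the striatal transcription factor gene Isl1 -2.81. Slc17a6, the vesicular glutamate transporter of many subcortical neurons, had -0.73, and the proliferation gene Top2a had -3.04. Without Scramble shRNA 3 the log2 fold change was -0.27 for Mag, -0.46 for Mog, -0.64 for Drd2, -0.56 for Adora2a and -1.72 for Isl1, and that of Isl1 was -5.26 without Npas4 shRNA 1.

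With all 7 libraries the camera adjusted p was 3e-06 for oligodendrocytes and 2.26e-04 each for striatal neurons and for olfactory bulb and subventricular zone. It was 4.05e-04 for thalamic and subcortical neurons and 0.00337 for choroid plexus and ependyma. Oligodendrocyte precursors had 0.00275, with the lineage gene Olig2 at a log2 fold change of -0.42. Without Scramble shRNA 3 none of these 6 lists passed, with adjusted p values of 0.224, 0.127, 0.0826, 0.128, 0.128 and 0.201 in the order named. Their score differences went from -0.367, -0.405, -0.539, -0.345, -0.383 and -0.205 to -0.099, -0.178, -0.252, -0.135, -0.218 and -0.076. With an estimated correlation they had adjusted p values of 0.436, 0.433, 0.325, 0.355, 0.433 and 0.433. Scramble shRNA 4 had the lowest oligodendrocyte score, -0.706, and without it the score difference of oligodendrocytes went from -0.367 to -0.655 (adjusted p = 9.77e-21). Within set A, which holds neither Scramble shRNA 3 nor 4, oligodendrocyte markers kept an adjusted p of 5.34e-08 with a score difference of -0.457. In set B the difference was -0.214. The single library labelled Npas4 shRNA there scored -0.079, between Scramble shRNA 3 at 0.964 and Scramble shRNA 4 at -0.706. The fits within set A and without Scramble shRNA 4 were not run with an estimated correlation. The other 5 lists did not pass within set A (0.388, 0.329, 0.615, 0.244 and 0.5 in the same order).

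With the library set as a term the calls of striatal neurons (0.0969), thalamic and subcortical neurons (0.0633) and oligodendrocyte precursors (0.156) were lost, at score differences of -0.423, -0.287 and -0.139. The others had 0.015 for oligodendrocytes and 0.0401 each for olfactory bulb and subventricular zone and for choroid plexus and ependyma. In that fit these 3 had an adjusted p = 0.792, 0.72 and 0.72 with an estimated correlation. The choroid plexus and ependyma call was lost with the set as a term and a correction for length and GC content (0.114). The median log2 fold change was -0.52 there against -0.60 without the correction. That call was kept with the replicate block and the correction (0.01). The precursor call became 0.0559 with the replicate block. The calls of striatal, olfactory, and choroid plexus and ependyma markers were also lost without Npas4 shRNA 3 (0.11, 0.0552 and 0.456), and that of precursors without Npas4 shRNA 2 (0.0632).

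**Figure D3:**
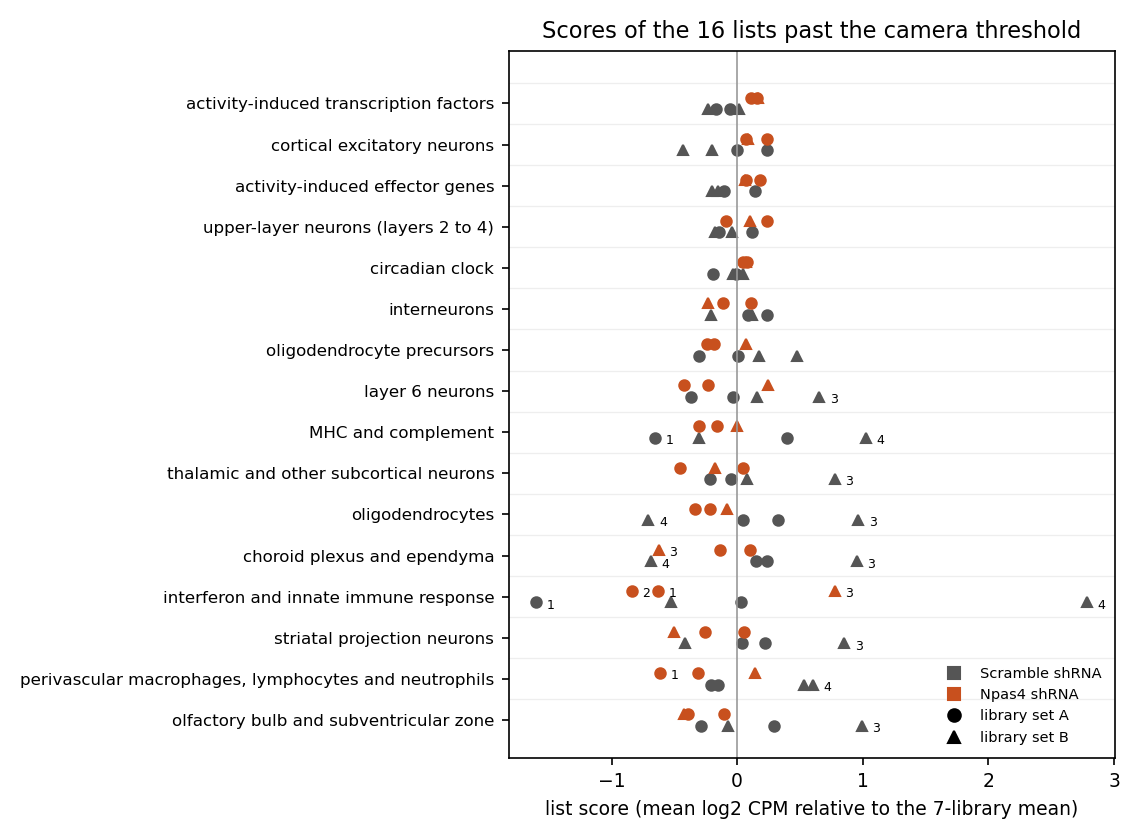
Scores of the 16 lists past the camera threshold in each library, on an axis of mean log2 CPM relative to the mean of the 7 libraries, with Scramble shRNA in grey, libraries labelled Npas4 shRNA in orange, marker shape for the library set, and replicate numbers beside scores beyond 0.6 in size. Scramble shRNA 3 lies at 0.964 for oligodendrocytes and 0.854 for striatal neurons, and Scramble shRNA 4 at 2.787 for interferon genes.

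Interferon-response genes were far higher in Scramble shRNA 4 than in any other library. The list of 39 genes scored 2.787 there, 0.776 in the library labelled Npas4 shRNA 3 and 0.032 or less in the other 5. Ifi44 stood at 103 CPM in Scramble shRNA 4 and at 5.07 CPM or less in the other Scramble shRNA libraries, and the guanylate-binding protein gene Gbp2 at 152 CPM against 18.7 CPM or less. Isg15 and Bst2, both induced by interferon, had log2 fold changes of -1.56 and -1.30 between the labels. Without Scramble shRNA 4 the log2 fold change was 0.78 for Ifi44, 0.22 for Gbp2, 0.05 for Isg15 and -0.43 for Bst2. All 39 genes had a log2 fold change below 0, and the camera adjusted p was 0.00188 (adjusted p = 0.808 with an estimated correlation). That direction rested on Scramble shRNA 4. Without it the list was higher in the libraries labelled Npas4 shRNA (adjusted p = 2.02e-04), as it was with the replicate block, in which that library has no partner (adjusted p = 0.00436, and an adjusted p = 0.8 with an estimated correlation). With the library set as a term the adjusted p was 0.549, and without Npas4 shRNA 1 or 2 it was 0.102 and 0.401. Genes of MHC and complement had an adjusted p of 0.011, with 21 of 24 below 0, an adjusted p = 0.71 with an estimated correlation and 0.944 without Scramble shRNA 4. The replicate block gave them 0.852, the library set as a term 0.141, and leaving out Scramble shRNA 2, Npas4 shRNA 2 or Npas4 shRNA 3 gave 0.398, 0.0903 and 0.0897. Markers of perivascular macrophages, lymphocytes and neutrophils had 0.00166 over 9 sparse genes and an adjusted p = 0.296 with an estimated correlation. They had 0.373 with the replicate block, 0.201 with the library set as a term, and 0.145, 0.0903 and 0.0518 without Scramble shRNA 3, Scramble shRNA 4 or Npas4 shRNA 2. Their score difference was -0.452 with all libraries and -0.314 with the block, and ranged from -0.871 to -0.27 over the left-out libraries.

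Ribosomal protein genes scored lower in the libraries labelled Npas4 shRNA once the library sets were separated. Their share of all counts was 3.56% and 3.70% in Scramble shRNA 1 and 2 against 2.93% and 3.02% in Npas4 shRNA 1 and 2. In set B it was 1.43% and 1.18% in Scramble shRNA 3 and 4 against 1.02% in Npas4 shRNA 3. Without the set in the model the list of 77 genes did not pass (adjusted p = 0.537, median log2 fold change -0.13). With the set as a term the median was -0.34, the adjusted p was 1.77e-30, and 64 of 77 genes passed when adjusted over the list alone. The list had an adjusted p = 0.72 with an estimated correlation in that fit and 0.793 with the block. After a correction for transcript length and GC content the median was -0.07 and the adjusted p 3.37e-04. The replicate block gave 2.47e-28, and 7.06e-04 with the correction. Camera gave 4.48e-22 within set A. In set B, with a single library labelled Npas4 shRNA, the median was -0.29, and 73 of 77 genes were below 0 in both sets. Rps20 had a log2 fold change of -0.49 with the set as a term. Nuclear-encoded genes of oxidative phosphorylation did not pass without the set in the model (adjusted p = 0.876). They had a median of -0.28 and an adjusted p of 1.08e-14 with the set as a term, and 1.22e-18 with the replicate block, with an adjusted p = 0.72 and 0.793 with an estimated correlation. With the correction the median was -0.03 and the adjusted p 0.434 with the set as a term, and 0.0402 with the block. Within set A the adjusted p was 6.89e-20, and in set B the median was -0.07. Sdha, a subunit of complex II, and Atp5b, of the ATP synthase, had log2 fold changes of 0.11 and -0.07 in the fit with the set as a term. Both lists hold short transcripts, with medians of 914 nt and 937 nt, the class of genes that differed most between the sets.

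The other lists did not pass in the comparison of all 7 libraries. Glutamatergic synapse genes had an adjusted p of 0.128, with log2 fold changes of 0.37 for the adhesion protein gene Lrrtm1 and 0.38 for the pentraxin receptor gene Nptxr (0.20 without Npas4 shRNA 3), and 0.015 with the set as a term and 0.0146 with the replicate block. These became an adjusted p = 0.72 and 0.793 with an estimated correlation, and 0.373 and 0.363 with a correction for transcript length and GC content. Voltage-gated ion channels had 0.202, 0.0326 with the set as a term and then an adjusted p = 0.72 with an estimated correlation, 0.0514 with the replicate block, and 0.486 with the set as a term and the correction. GABAergic synapse genes had 0.863. Synaptic vesicle genes had 0.409, with Synpr at 0.50 and Rab3c at -0.26. Neuropeptide genes had 0.887, with neurotensin (Nts) at -2.51, and monoamine and acetylcholine receptors had 0.775, with the adrenergic receptor gene Adra1d at 0.82 (0.51 without Npas4 shRNA 3). Glucocorticoid-induced genes had an adjusted p of 0.535, reactive glia 0.883, the p53 and DNA damage response 0.0869, and protein folding 0.299. Cholesterol synthesis had 0.24, the neuronal cytoskeleton 0.428 and the RNA interference machinery 0.43. Among cell types, astrocytes had 0.0869, with the filament gene Gfap at a log2 fold change of -0.51 (from -1.07 without Npas4 shRNA 1 to -0.30 without Npas4 shRNA 3), microglia 0.43, endothelial cells 0.346, pericytes and smooth muscle 0.116, fibroblasts and meninges 0.799, and red blood cells 0.158. With the length and GC correction 3 of these lists passed as higher, both with the set as a term and with the replicate block. They were endothelial cells (0.0194 and 0.01), the p53 response (0.0194 and 0.0146) and red blood cells (0.0295 and 0.01). Cholesterol synthesis passed as lower with the set as a term (0.0397) and not with the block (0.289). The corrected fits were not run with an estimated correlation. The median, the mean and the camera direction differed in sign for 9 lists that did not pass. These were NPAS4 targets, bHLH-PAS genes, GABAergic synapse, monoamine receptors, oxidative phosphorylation, the neuronal cytoskeleton, layer 5, microglia, and fibroblasts and meninges.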

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

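Ifit1, Mbp and Gabrb2 were chosen after their values were seen, and the other genes were named by the rule fixed beforehand. Values of the 4 Scramble shRNA libraries were examined for a single library far from the other 3, over 104 list scores, gene levels and library measures in the text. In 7 of them 1 library's gap to its nearest neighbour, as a share of the whole range, exceeded Dixon's 95% critical value for 4 samples. Chance picks out about 1 in 20, or 5.2 of 104, if the 4 libraries are exchangeable. They fall 2 and 2 into the library sets, and the 7 values are not independent, so that count is a rough guide. Interferon-response genes in Scramble shRNA 4 gave 3 of the 7. There Ifi44 stood at 103 CPM, Gbp2 at 152 CPM and Ifit1 at 124.1 CPM, against at most 5.07, 18.7 and 10.2 CPM in the other Scramble shRNA libraries. Of the 4 Scramble shRNA libraries, the same library had the most Nptxr, at 1215 CPM against 769 to 822 CPM. Scramble shRNA 3 had the most Ctgf, at 50.68 CPM against 15.1 to 17.0 CPM, and the most Cdca3, at 2.75 CPM against 0.933 to 1.24 CPM. Scramble shRNA 1 had the most Egr3, at 157.5 CPM against 111 to 116 CPM.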

How the results depend on the processing

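Settings that use the library sets, alone or with a length and GC correction, were chosen after seeing the data. The counts of 0 genes past the threshold, 0 higher and 0 lower, held under every alternative run, and over the left-out libraries they ranged from 0 to 0. Unadjusted p values below 0.05 ranged from 41 to 119 genes over the left-out libraries. For Npas4 the log2 fold change ranged from -0.367 to 0.339 over the left-out libraries, below 0 without Scramble shRNA 2 or Npas4 shRNA 3, was -0.135 in library set A only, and stayed above 0 under the other alternatives, at 0.265 with the replicate block. The 16 gene lists past the threshold were 0 with camera's estimated correlation and 0 with fry, 3 in library set A only and 9 with the library set term without Scramble shRNA 3. Over the left-out libraries they ranged from 9 to 22, and the lowest was without Scramble shRNA 3, where 11 of the 16 calls were lost. Without Npas4 shRNA 2 there were 10. Under the other alternatives they were 11 to 18, and 13 with the replicate block, which lost 7 calls, turned 1 and added 4. It changed no call of a gene. Differences in list score that changed sign with a list past the threshold with all libraries or under the alternative were these, and scores of other lists also crossed 0 where neither fit passed. Interferon genes, -0.403 with all libraries, were 0.468 with the replicate block, 0.499 with the block and length and GC correction, 0.049 in set A only, 0.458 with the set term without Scramble shRNA 4, and -0.995 to 0.458 over the left-out libraries. MHC and complement genes, -0.273 with all libraries, were 0.029 with the replicate block, 0.156 with the block and the correction, 0.03 with the set term without Scramble shRNA 4, and -0.53 to 0.03 over the left-out libraries. Oxidative phosphorylation genes, 0.010 with all libraries, were -0.313 with the replicate block, -0.035 with 1 surrogate variable, -0.247 with the set term, -0.364 in set A only, -0.068 with the block and the correction, -0.22 and -0.313 with the set term without Scramble shRNA 3 or 4, and -0.313 to 0.464 over the left-out libraries. Ribosomal protein genes, -0.045 with all libraries, ranged from -0.375 to 0.501 and fibroblast genes from -0.233 to 0.392 over the left-out libraries. GABAergic synapse genes, -0.007 with all libraries, were 0.072 in set B only. The labels are unevenly spread over the sets with all 7 libraries, evenly without Scramble shRNA 3 or 4 or Npas4 shRNA 1 or 2, and less evenly without the others, which by construction moves the lists of short transcripts. For the other turns the cause was not tested, apart from the interferon level of Scramble shRNA 4. Lists under all alternatives gave 751 values that held, 144 that lost a call, 66 that gained a call, 22 that turned and 1 that moved, by the direction of the test, which can differ from the sign of the score. Named genes other than Npas4 gave 1332 values within 1 SD and 35 beyond it, and none crossed the threshold. A change of sign of a gene or list that did not pass in either fit counts here as moved or not by its size. On simulated counts 1 of 100 2-fold changes was recovered without the set in the model and 76 with it, and depth was not varied.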

Other observations

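Chosen after their results were seen were the tests on the activity genes, on counting error and on Npas4 relative to the activity genes. So were those on ribosomal protein and oxidative phosphorylation genes corrected for length and GC content or within a single library set. The others were set before their own results were seen. Those of them that use the library sets came after the data had been examined, since the sets were read from the data.

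Some gene groups varied between libraries with the same label. Markers of fibroblasts and meninges scored 0.65, -0.995, 0.797 and -0.602 in Scramble shRNA 1 to 4 and -0.372, -0.09 and 0.612 in Npas4 shRNA 1 to 3. In library set A the interferon score ran from -1.598 in Scramble shRNA 1 to 0.032 in Scramble shRNA 2, so interferon genes differed between libraries outside Scramble shRNA 4 as well. Genes of MHC and complement scored -0.654 and 0.4 in the same 2 libraries and 1.023 in Scramble shRNA 4. Layer 6 markers scored 0.655 in Scramble shRNA 3 and 0.247 or less in the other 6 libraries.

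Npas4 was not lower in the libraries labelled Npas4 shRNA. Counting error is argued against as the reason that a fall to 0.5 of the control level was missed, since the counting interval of the ratio of pooled CPM, 1.12, reached from 1.025 to 1.233 on 847 and 1011 counts. A fall hidden by more activity-induced transcription could not be told apart from no fall. Npas4 minus the score of the other activity-induced transcription factors differed by -0.176 on the log2 scale, with an exact permutation p of 0.657. That test takes no account of the library sets. The log2 fold change of Npas4 itself was -0.13 within set A and 0.61 within set B, which holds a single library labelled Npas4 shRNA. A small share of transduced cells in the tissue pieces, a hairpin acting on translation and a wrong label stay open and were not tested.

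Activity-induced transcription factors scored higher in the libraries labelled Npas4 shRNA. Other tissue in Scramble shRNA 3 was examined by leaving that library out. The camera adjusted p was 0.00105 and the score difference 0.212, against 0.253 with all libraries. Transcript length and GC content were examined by correction with the set as a term. The camera adjusted p was 0.000215, and the median log2 fold change went from 0.28 to 0.27. Most of the size was thus kept in both fits. Both p values are at the preset correlation, and neither fit was run with an estimated correlation, so these calls cannot decide against either cause. In the uncorrected fits of all libraries an estimated correlation ended the list's call (adjusted p = 0.155, and 0.72 with the set as a term), as did fry (0.807). A larger share of cortical excitatory neurons cannot be told apart from other causes, since with the score of these neurons subtracted 9.451% of the score difference was left over all libraries (-25.71% to 44.34% leaving out each), but 85.87% in set A and -47.92% in set B, which holds a single library labelled Npas4 shRNA. A biological effect of the hairpin stays open as a hypothesis, and with Npas4 not lower it has no measured link to the target.

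Ribosomal protein genes scored lower in the libraries labelled Npas4 shRNA with the library set as a term, and most of the size went with length and GC content, the median going from -0.34 to -0.07 on correction (adjusted p = 3.37e-04, and without the correction an adjusted p = 0.72 with an estimated correlation). Of 1000 lists of other genes matched on length, GC content and expression, 0% had a median as low (lowest -0.28). The matched genes, 421 distinct ones, were somewhat longer, with a median of 961 nt against 914 nt. Shorter transcripts were lower in this comparison, so the imperfect match works toward a share of 0%. Genes matched in this way did not reach the whole size. They were drawn singly, so their lists leave out any joint variation of ribosomal protein genes between libraries. The test therefore cannot decide whether what is left beyond length and GC content is more than such variation. For oxidative phosphorylation genes 0% were as low as -0.28 with the set as a term (lowest -0.27), and in set A 0% were as low as -0.41 (lowest -0.34). The same limits hold here, with matched genes at a median of 983 nt against 937 nt, and with the set as a term the margin was narrow. Length and GC content as the whole cause therefore stay undecided. The correction took the median of oxidative phosphorylation genes to -0.03. It ended the call with the set as a term (adjusted p = 0.434) but not with the replicate block (adjusted p = 0.0402). Without the correction an estimated correlation also ended both calls (adjusted p = 0.72 and 0.793). In set B, with a single library labelled Npas4 shRNA, 71.9% of matched lists were as low. There the median of -0.07 was no lower than the -0.09 of the matched lists. The list was thus no lower than genes of like length and GC content in that set. With a single library labelled Npas4 shRNA there, this cannot tell whether length and GC content are the cause.

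Other splits of the 7 libraries were fitted in the same way. For single genes the real split gave 0 (edgeR, 61 at an unadjusted p below 0.05, with DESeq2 at 126 and limma-voom at 58), so 35 of 35 splits gave as many by construction, which says nothing about chance. The highest other gave 8817 genes and was the split by library set. The split of Scramble shRNA 1 and 2 and Npas4 shRNA 2, all of set A, from the rest gave 4861. The sets were read from these same values, so the 8817 describe the largest difference among the libraries and do not test it. With the library set as a term the highest other split gave 1 gene. For lists the real split gave 16 and the highest other 24, with 8 of 35 splits giving as many, so chance is not excluded. With the library set as a term the real split gave 12 lists and the highest other 21, with 10 of 18 splits as many. With the replicate block it gave 13 and the highest other 20, with 4 of 8 splits as many. The 18 and the 8 splits are too few to give a share below 0.05.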
